A study of Ovis aries with 12 samples.

How the data were processed

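Gene expression was measured by RNA sequencing in longissimus muscle, the long muscle of the back, from Suffolk by Texel crossbred sheep. There were 12 libraries, 3 at each of 4 ages. The ages were days 85 and 133 of gestation (G85 and G133) and days 42 and 243 after birth (D42 and D243). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected, and libraries were made with an NEBNext Ultra II kit; strandedness is not given in the sources used here.

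The authors deposited 1 table of CPM (read counts scaled to a library total of 1000000) for 15743 genes in the 12 libraries. FastQC 0.11.9, Trim Galore 0.6.6, RSEM 1.3.3, Subread featureCounts 2.0.2 and edgeR 3.34.1 are named per the submitters' processing notes, without roles or order. The genome build, annotation and read layout are not given in the sources used here. Every column sums to 1000000, so the deposited CPM carry no further between-library scaling factor such as a trimmed mean of M values (TMM) factor. Every gene exceeds 1 CPM in at least 3 libraries (the lowest third-highest value of any gene is 1.003), and the totals were taken after that filter. The values above 0 were whole multiples of 1 step per library: 100% of 188642 values lay within 0.01 reads of a whole number. The recovered totals were 10556715 to 23255962 reads per library, so 1 read was worth 0.043 to 0.0947 CPM. These totals cover only the genes kept in the table.

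Genes are named in the table by Ensembl identifiers alone. None of the 15743 identifiers (0) matched the identifier, synonym or locus tag columns of the RefSeq gene table used here (assembly ARS-UI_Ramb_v3.0), and the files do not pair them with symbols. Gene names, coordinates and the 27 gene lists fixed before the data were examined were therefore not used, nor were the set tests planned on them. The rule for named genes also had to be applied without symbols. It took, per step between adjacent ages, the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05 and a mean of at least 10 CPM. Of these, only the 2 largest rises and 2 largest falls over the 3 steps are printed by identifier; the others are summarised.

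CPM were tested on the log2(CPM + 1) scale, which understates the change of low genes, with limma 3.58.1 in R 4.3.3. One model with age as its only term was fitted to all 12 libraries, with a mean-variance trend and 8 residual degrees of freedom. The differences G133 minus G85, D42 minus G133 and D243 minus D42 were tested, together with an F test over the 4 ages. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 15743 genes, with a threshold of 0.05. The planned filter of 1 CPM in 3 libraries removed 0 genes. Because CPM are shares of a fixed total, the counts of changed genes per step and over the 4 ages are also given after a rescaling. Each library was rescaled by the median, over genes, of its ratio to the geometric mean. This is called the median-ratio scale below. The rescaling shifted the median gene by more than 0.1 on the log2 scale at each step, as given with each comparison.

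Shares of reads held by abundant genes were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest p is 0.1, so a pair of ages cannot reach 0.05. All 369600 assignments of the 12 libraries to the 4 ages were enumerated for the comparison of all ages. These tests treat the libraries as independent and do not pair D42 with D243 by animal. No 2 replicates agreed within sampling noise: the chi-square per degree of freedom between replicates of an age was 12.6 to 149.

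The replicate numbers in the titles recur at every age. The descriptions carry a further number that recurs only between D42 and D243, read here as the animal; no label states it. The deviations of same-numbered D42 and D243 libraries from their age means correlated across genes at 0.193, 0.163 and 0.174, against -0.131 to -0.041 for libraries with different numbers. Deviations from a mean of 3 sum to 0, so positive values for the same numbers push the others below 0. Libraries with no animal number in common reached 0.327 (G85 and G133 replicate 1), so such a size alone does not mark a shared animal. Only between D42 and D243 did all 3 same-numbered pairs exceed every other pair. With the recurring numbers, this was taken to pair D42 with D243. The fit reported has no block, and the fit with the animal as a block was an alternative. No other pair of ages shared animal numbers.

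The alternatives covered the pseudocount, the filter, the scaling, the moderation of variances, the samples in the fit, the blocks and leaving out each library in turn. Count models were run on the recovered reads: edgeR 4.0.16 quasi-likelihood with TMM factors called 4742, 5032 and 1734 genes at the 3 successive steps, and DESeq2 1.42.0 called 5205, 5329 and 2324. The main test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, at a dispersion of 0.0352. The changed genes had a mean of at least 10 CPM, with as many rises as falls. All other genes kept the same mean at every age, and all genes had the same dispersion. The simulation therefore held no shift of reads towards abundant genes, and does not show how many calls such a shift gives in CPM. For G85 to G133 it recovered 83% of 2-fold and 100% of 4-fold changes, with 4 calls among 15336 unchanged genes. For G133 to D42 it recovered 82% and 100%, with 14 calls among 15327. For D42 to D243 it recovered 78% and 100%, with 8 calls among 15319. Counting error only is covered by any statement on depth, since reads without molecular identifiers are not independent molecules.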

Results

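The transcriptome of sheep longissimus muscle was followed over 2 fetal ages (G85 and G133) and 2 postnatal ages (D42 and D243), with 3 libraries at each. The recovered totals ranged from 15637901 to 21793358 reads at G85, from 15673716 to 23255962 at G133, from 10556715 to 18319851 at D42 and from 16662916 to 21300818 at D243. The smallest library was D42 replicate 1. Between 0.0318% and 0.381% of the 15743 genes had no read in a given library. Genes are identified in the data by Ensembl identifiers only, so they are described here by abundance, by direction and, for 4 of them, by identifier. Libraries within an age carry different animal numbers, and D42 and D243 carry the same 3. The p-values measure the spread between these libraries.

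A small number of highly expressed genes took up a growing part of the muscle transcriptome between G85 and D42. The 50 most abundant genes of each library held 18.95% ± 1.04 of its reads at G85, 27.2% ± 1.41 at G133, 45.8% ± 0.6 at D42 and 46.7% ± 3.04 at D243 (SD, n = 3 each). One gene was the most abundant in all 12 libraries. Its share was 2.44% ± 0.587 at G85, 4.46% ± 0.255 at G133, 11.3% ± 1 at D42 and 11% ± 1.41 at D243. The abundance of the median gene moved the other way, from 21.2 ± 1 CPM at G85 to 15.8 ± 1.44 at G133, 12.7 ± 0.37 at D42 and 10.8 ± 0.836 at D243.

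The share of the top 50 genes differed among the 4 ages (exact permutation p = 0.000519, adjusted p = 0.000649 over 5 such measures). The median CPM did so as well (exact permutation p = 6.49e-05, the smallest that 369600 arrangements allow; adjusted p = 0.000324). From G85 to G133 and from G133 to D42 the libraries of the 2 ages did not overlap for the top 50 share. Each pair gave the smallest possible exact p of 0.1, with mean differences of 8.29 and 18.6 percentage points. From D42 to D243 the mean difference was 0.877 points (exact permutation p = 0.8), with the D243 libraries ranging from 43.8% to 49.8%. By animal number the share went from 46.51% to 46.49%, from 45.53% to 43.77% and from 45.42% to 49.83%. The permutation tests leave out this pairing and treat all 12 libraries as independent, so their p-values are approximate.

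**Figure D1:**
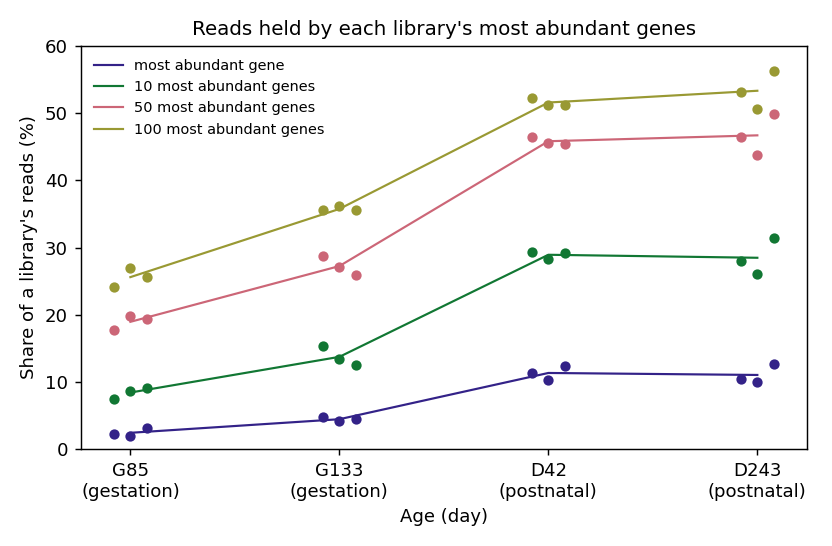
Share of each library's reads (%) held by its most abundant gene and by its 10, 50 and 100 most abundant genes, by age. Points are the 3 libraries of an age and lines join the age means; the 50-gene share is 18.95% at G85 and 45.8% at D42, and the D42 and D243 libraries overlap.

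The fetal and postnatal libraries lay in order of age along the first principal component, but G133 stood apart on the second. There G133 replicates 2 and 3 lay at -48.42 and -50.23 and replicate 1 at -13.41. The libraries of the other ages lay between 5.178 and 24.64. The first principal component of log2(CPM + 1) held 75.1% of the variance and the second 9.48%. Distances between libraries were taken as the root mean square log2 difference over genes. Their means were 0.807 between G85 and G133, 0.754 between G133 and D42 and 0.519 between D42 and D243 (0.7, 0.69 and 0.501 on the median-ratio scale). Within an age they were 0.315 at G85, 0.421 at G133, 0.312 at D42 and 0.415 at D243. G133 replicate 1 lay at a mean distance of 0.478 from the other 2 G133 libraries, which were 0.308 apart. Of the 15743 genes, 13931 changed over the 4 ages (limma F test, adjusted p under 0.05), or 88.5%; on the median-ratio scale 9874 did, or 62.7%. Of the 9874, 37.8% had their highest mean at G85, 14.9% at G133, 12.2% at D42 and 35.1% at D243; as deposited, 77.1% of the 13931 had it at G85.

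**Figure D2:**
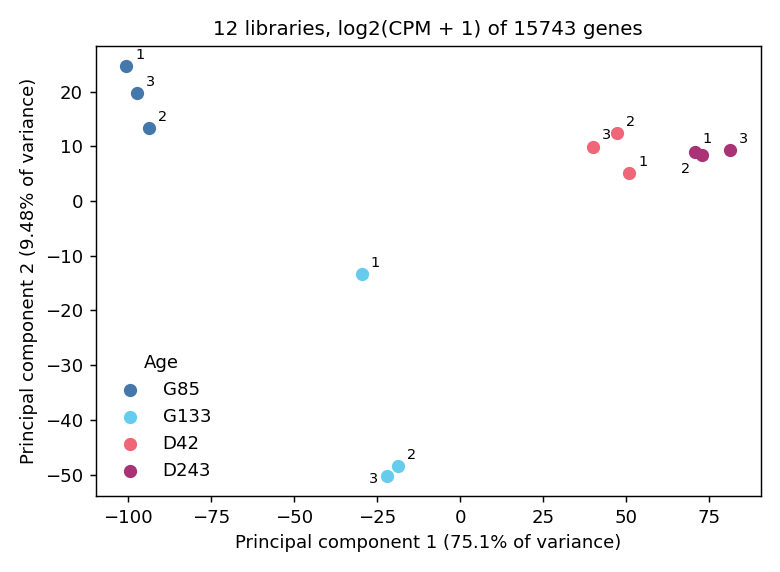
The 12 libraries on the first and second principal components of log2(CPM + 1) over 15743 genes; the axes give each component's share of the variance, colours give the age and numbers the replicate. Ages follow one another along the first component (75.1% of the variance), and G133 replicate 1 lies apart from the other G133 libraries on the second.

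The step from G85 to G133 addressed change within fetal muscle from mid to late gestation. As deposited, which way the most abundant genes went depended on the age by which they were ranked. Ranking by the earlier of 2 ages favours genes that then fall, and ranking by the later age favours genes that rose. Ranked by G85, 13 of the top 50 rose and 23 fell (16 and 10 on the median-ratio scale), and ranked by G133, 26 rose and 6 fell (30 and 0). On the median-ratio scale rises thus outnumbered falls by either ranking. Ranks by the mean over all 12 libraries favour genes that are high at the postnatal ages, so rises are partly built into them. Of the top 50 by that mean, 32 rose, 7 fell and 11 did not pass the test, with a median log2 change of 0.85; on the median-ratio scale 36 rose and 1 fell, and by quantile normalization 21 rose. A fit to the 6 libraries of these ages alone called 2 falls. Of the 450 genes next in abundance, 124 rose and 89 fell, or 198 and 43 on the median-ratio scale. The 4500 genes after these showed 418 rises and 2279 falls as deposited, but 855 rises and 725 falls on that scale. The 10743 genes below rank 5000 showed 421 rises and 4893 falls, or 930 and 1672. ENSOARG00000011052 had the largest rise at any step, from 21.7 ± 3.5 CPM at G85 to 1294 ± 361 at G133 (SD, n = 3 each), a log2 change of 5.80 ± 0.211 (SE; limma adjusted p = 3.58e-09). ENSOARG00000014513 had the largest fall, from 217.8 ± 25.4 to 3.35 ± 0.707 CPM, a log2 change of -5.66 ± 0.261 (limma adjusted p = 1.68e-08). ENSOARG00000011750 fell from 692.2 ± 143 to 26.2 ± 9.17 CPM, a log2 change of -4.71 ± 0.361 (limma adjusted p = 6.79e-07). The 6 largest rises in the rule for named genes spanned log2 changes of 3.88 to 5.80, and the 6 largest falls -4.51 to -5.66.

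In all, 8263 genes changed from G85 to G133, 995 higher and 7268 lower at G133 (limma, adjusted p under 0.05). The median gene's log2 change was -0.37. On the median-ratio scale, which sets that median near 0, 4460 genes changed, 2019 higher and 2441 lower. Of the rises as deposited, 988 were also called on that scale, as were 2441 of the falls, and 0 genes were called in opposite directions. Changes of at least 2-fold on the median-ratio scale numbered 769 higher and 717 lower. The 12 genes with the largest changes kept their direction and passed the test on both scales. The rescaling moves all genes of a library by nearly the same amount. At any step, opposite calls or a turn of the largest changes were therefore unlikely from the start.

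The step from G133 to D42 spans birth and compared late fetal with early postnatal muscle. Between the mean profiles of the 2 ages, 31.6% of reads changed place, against 24.8% from G85 to G133 and 10.8% from D42 to D243. Between single libraries the figure was 25.6% to 38.5%, overlapping the 23.6% to 30.2% from G85 to G133, and 11.1% to 14.3% from D42 to D243. Between replicates of an age it was 6.11% to 19.9%, the highest at G133. The 50 genes that gained most, chosen by that gain, held 79.4% of all gains. Ranked by G133, 19 of the top 50 genes rose and 19 fell (19 and 18 on the median-ratio scale), and ranked by D42, 35 rose and 2 fell (36 and 1). By the mean over all libraries 27 rose and 10 fell, with a median log2 change of 0.78, and 27 and 9 did on the median-ratio scale; by quantile normalization 17 rose. Of the next 450, 96 rose and 255 fell, with a median of -0.67, and on the median-ratio scale 133 rose and 201 fell. The 4500 genes after these showed 518 rises and 1907 falls, or 1106 and 645 on the median-ratio scale. The 10743 genes below rank 5000 showed 636 and 4003, or 1489 and 1491. ENSOARG00000003501 had the largest rise of this step, from 26.4 ± 8.88 to 1101 ± 379 CPM (SD, n = 3 each), a log2 change of 5.33 ± 0.245 (SE; limma adjusted p = 2.75e-08). ENSOARG00000011750 fell further, from 26.2 ± 9.17 to 0.9 ± 0.164 CPM, a log2 change of -3.78 ± 0.361 (limma adjusted p = 8.23e-06). ENSOARG00000014513 fell from 3.35 ± 0.707 to 0.881 ± 0.188 CPM (log2 change -1.20 ± 0.261, limma adjusted p = 0.00244). ENSOARG00000011052 stood at 1828 ± 104 CPM at D42; its log2 change of 0.54 ± 0.211 passed the test narrowly (limma adjusted p = 0.0495). That call was lost in 13 of 29 alternatives, over which the adjusted p ran from 3.9e-05 to 0.196. Among them were the fit with the animal as a block (limma adjusted p = 0.0708) and the removal of G133 replicate 3 (log2 change 0.28, adjusted p = 0.196), of any G85 or D42 library, or of D243 replicate 1 or 3 (adjusted p of 0.0565 to 0.118). At every called step of these 4 genes, each of the 3 libraries of the later age lay beyond all 3 of the earlier age. The genes were picked by their largest change in these same libraries, so at the steps that picked them this adds no support.

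From G133 to D42, 7452 genes changed, 1277 higher and 6175 lower at D42 (limma, adjusted p under 0.05), with a median log2 change of -0.33. On the median-ratio scale 5101 changed, 2755 higher and 2346 lower, so the side with more genes differs between the scales. Both scales shared 1276 rises and 2346 falls. The 6 largest rises by the rule spanned 3.91 to 5.33 on the log2 scale and the 6 largest falls -3.27 to -4.20; each kept its direction and passed on the median-ratio scale.

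**Figure D3:**
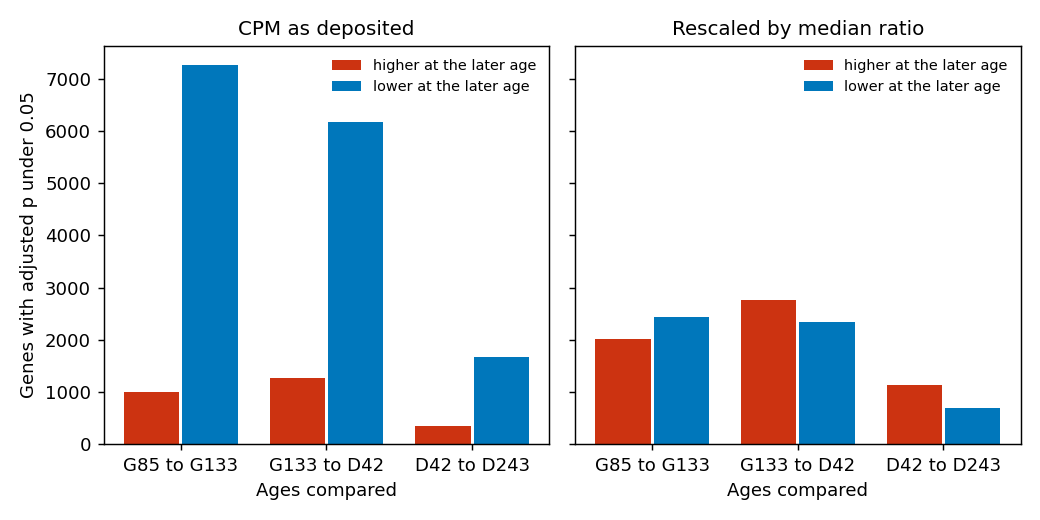
Number of genes higher or lower at the later of 2 adjacent ages (limma, adjusted p under 0.05) from CPM as deposited and after rescaling by median ratio. Lower genes outnumber higher ones at all 3 steps as deposited (7268 against 995 from G85 to G133), and higher genes outnumber lower ones at the last 2 steps after rescaling (2755 against 2346 and 1138 against 700).

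The step from D42 to D243 compared early postnatal muscle with muscle at the oldest age. Fewer genes changed than at the earlier steps, and the most abundant ones mostly did not pass the test. Ranked by D42, 1 of the top 50 rose and 1 fell (3 and 0 on the median-ratio scale), and ranked by D243, 5 rose and 0 fell (7 and 0). By the mean over all libraries 1 rose, 5 fell and 44 did not pass. On the median-ratio scale 3 of them rose and 0 fell, and by DESeq2 13 rose. Rises ranged from 0 to 4 as each library was left out: 0 without D42 replicate 1 or 3 or D243 replicate 1 or 3, 3 without G133 replicate 3 and 4 without G133 replicate 1. With the animal as a block 1 fell, and the falls numbered 0 without D42 replicate 2 or 3 or D243 replicate 1 or 3, 1 without G85 replicate 1, D42 replicate 1 or D243 replicate 2, and 3 without G85 replicate 3 or G133 replicate 2. Of the next 450, 28 rose and 25 fell, or 59 and 7 on the median-ratio scale, and of the 4500 after these 167 rose and 496 fell, or 522 and 193. The 10743 genes below rank 5000 had 154 rises and 1153 falls, or 554 and 500. ENSOARG00000003501 rose again, from 1101 ± 379 to 3392 ± 633 CPM (SD, n = 3 each), a log2 change of 1.66 ± 0.245 (SE; limma adjusted p = 0.00157). It had also risen from 8.55 ± 0.141 CPM at G85 to 26.4 ± 8.88 at G133 (log2 change 1.47 ± 0.245, limma adjusted p = 0.000311), so it rose at every step. ENSOARG00000011750 went from 0.9 ± 0.164 to 4.25 ± 3.48 CPM (log2 change 1.27 ± 0.361, limma adjusted p = 0.035). Its D243 libraries ranged from 1.78 to 8.22 CPM, and the call was lost in 9 of 29 alternatives, over which the adjusted p ran from 2.84e-05 to 0.128. Leaving out D243 replicate 1 gave 0.77 (limma adjusted p = 0.109), D243 replicate 3 gave 1.42 (0.0565), and D42 replicates 1, 2 and 3 in turn gave 1.25 (0.08), 1.34 (0.0755) and 1.22 (0.103). ENSOARG00000011052 stood at 2168 ± 298 CPM at D243 (log2 change 0.24 ± 0.211, limma adjusted p = 0.445). By DESeq2 its change passed narrowly (0.51, adjusted p = 0.0497, the lowest of 29 alternatives, which reached 0.911), and on the median-ratio scale it was 0.50 (limma adjusted p = 0.117). The level of ENSOARG00000014513 was 1.08 ± 0.929 CPM (log2 change 0.04 ± 0.261, limma adjusted p = 0.92), on as few as 4 reads in a library.

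From D42 to D243, 2029 genes changed, 350 higher and 1679 lower at D243 (limma, adjusted p under 0.05), with a median log2 change of -0.20. On the median-ratio scale 1838 changed, 1138 higher and 700 lower. Both scales shared 350 rises and 694 falls. The 6 largest rises by the rule spanned 2.32 to 3.90 on the log2 scale and the 6 largest falls -2.09 to -2.75. The count varied as single libraries were left out. As deposited it was 957, 2169 and 1172 without D243 replicates 1, 2 and 3. Without D42 replicates 1, 2 and 3 it was 1393, 962 and 919. Leaving out a library of this step also lowers the power of the test, which was not told apart from the weight of that library. Without G133 replicate 1, which is not in this comparison, it was 3046. Such a library acts only through the spread estimated over all 12 libraries and the adjustment that follows. Without D42 replicate 1 the rises numbered 212.

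**Figure D4:**
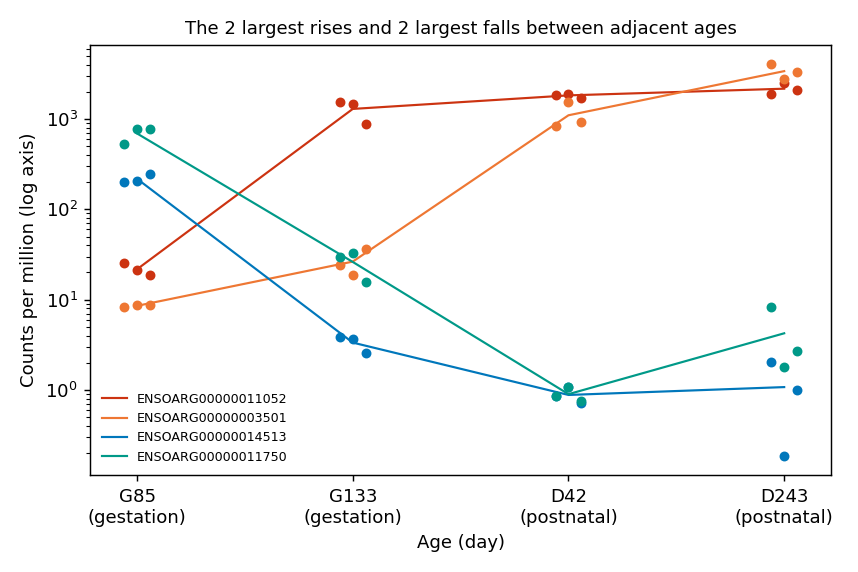
Expression in CPM (log axis) of the 2 genes with the largest rises and the 2 with the largest falls between adjacent ages, by age; points are the 3 libraries of an age and lines join the means. ENSOARG00000011052 rises from 21.7 to 1294 CPM between G85 and G133, ENSOARG00000003501 from 26.4 to 1101 CPM between G133 and D42, and both falling genes drop between G85 and G133.

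Taking the 3 steps in sequence on the median-ratio scale, 7476 genes (47.5%) passed the test at no step. Falls at the first step alone were called for 1425 genes and rises at that step alone for 804. At the step across birth alone, 1408 genes fell and 1335 rose. At the last step alone, 328 rose and 237 fell. Rises at all 3 steps were called for 175 genes and falls at all 3 for 58. Calls that turned between the first and second step, with none at the last, were a rise then a fall for 295 genes and a fall then a rise for 247. As deposited, 3634 genes passed at no step, 17 rose at all 3 and 480 fell at all 3. Adjacent steps share the libraries of the middle age. With no effect at all, that sharing gave a correlation of -0.499 between the changes of adjacent steps in 20 simulations, against 0.143 and 0.0751 observed on the median-ratio scale. The observed covariances were 0.0577 and 0.0188, against a simulated -0.0186 for each. With the 3 libraries of the middle age divided between the steps, 1 and 2, the correlation over the 6 divisions was 0.0969 to 0.353 for the first pair of steps and 0.0666 to 0.191 for the second.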

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

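The thinning of libraries, and the removal of single libraries and the animal block on the median-ratio scale (overlaps of steps included), the ranks by a single age and the division of a middle age between steps were chosen after seeing the data. The split into higher and lower genes moved with most of the scalings. By median ratio, counts were 2019 higher and 2441 lower of 4460 from G85 to G133, 2755 and 2346 (5101) from G133 to D42, and 1138 and 700 from D42 to D243. By quantile normalization they were 2144 and 2603 (4747), 2601 and 2599, and 665 and 665 (1330). With edgeR on recovered reads they were 2282 and 2460 (4742), 2744 and 2288, and 1126 and 608. With DESeq2 they were 2503 and 2702 (5205), 2868 and 2461, and 1459 and 865; 62 genes per step had no adjusted p. Another setting removed the 50 genes most abundant by the mean over all 12 libraries. Its counts were 3870 lower from G85 to G133 (5136 in all), and 2722 higher and 1965 lower from G133 to D42 (4687). From D42 to D243 they were 382 and 1684 (2066), near the deposited 350 and 1679. The cause was not tested for each scaling.

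Stricter thresholds called fewer genes by construction. At least 2-fold left 427 higher and 1611 lower of 2038 from G85 to G133, 432 and 1380 of 1812 from G133 to D42, and 127 and 271 of 398 from D42 to D243. An adjusted p under 0.01 left 699 higher and 4541 lower of 5240, 772 and 3672 of 4444, and 136 and 459 of 595. Without each library in turn, calls from D42 to D243 ranged from 919 to 3046, with 195 to 509 higher and 716 to 2537 lower; the calls of the other steps and of the F test stayed within 1.5 times. On the median-ratio scale those from D42 to D243 ranged from 997 (without D42 replicate 2) to 2323 (without G133 replicate 1), and were 1086 without D243 replicate 1 and 1195 without D42 replicate 3; without D42 replicate 1 the higher genes were 707. With the animal as a replicate block, the pairing called 1897 genes from D42 to D243 (1858 on the median-ratio scale); beyond the results given with it in the report, it changed no other call of a named gene and moved no other count by over 1.5 times. The animal as a random effect called 3004 genes at that step, 484 higher and 2520 lower, at a correlation of 0.168 within animals. In such a model a positive correlation narrows the SE of a difference between ages of the same animals. Only this step shares animal numbers. The steps from G85 to G133 and from G133 to D42 gave 8255 and 7420 calls, against 8263 and 7452 without the effect. The replicate number as a block over all ages, which pairs no fetal animals, gave 8092, 7355 and 1881 calls. The equal-total and no-filter settings changed nothing, since both already held. The gene lists and their set tests were not run, for want of gene symbols. No called change of the 4 named genes turned in any alternative. Over all genes, directions were compared only between the deposited and the median-ratio scale, where no gene called on both turned. That rescaling moves all genes of a library nearly alike, so a turn was unlikely and its absence adds little. Depth limits the lowest genes most: 1 read is worth 0.0947 CPM in the smallest library.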

Other observations

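Tests on G133 replicate 1, the rule for genes switched on or off, the overlaps without single libraries on the median-ratio scale and the splits of 2 steps that part the animals were chosen after the results were seen. Few genes crossed the whole range between adjacent ages. From G85 to G133, 1 gene went from under 1 CPM in every library to at least 10 CPM in every library, and 4 went the other way. From G133 to D42, 0 were switched on and 1 off, and from D42 to D243, 0 and 0. The median spread of a gene between replicates, as an SD on the log2 scale, was 0.146 at G85, 0.165 at G133, 0.146 at D42 and 0.166 at D243 on the median-ratio scale.

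Genes lower at the later age outnumbered higher ones at each step as deposited, with median log2 changes of -0.37 (SE 0.0861), -0.33 (SE 0.0687) and -0.20 (SE 0.0547). After thinning every library to the smallest, the medians were -0.37, -0.33 and -0.20. CPM already divide by the library total, and thinning leaves each gene's expected CPM unchanged. Little other outcome was possible, so thinning does not decide whether a difference in depth had a part. Crowding was tried by removing the 50 genes most abundant by the mean over all 12 libraries. That ranking favours genes high at the postnatal ages, so the set was not neutral between the steps. Crowding by these 50 genes could account for the whole shift from G133 to D42, where removing them left a median of 0.0409 (SE 0.091). From G85 to G133 the median left was -0.20 (SE 0.105), inside 2 SE of 0 by a narrow margin, so that explanation stays open and so does a remainder. From D42 to D243 the median left was -0.21 (SE 0.0168), so those 50 genes were not the whole cause there, and crowding by other genes or a fall of many transcripts with age remains open, since CPM hold no absolute scale.

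G133 replicate 1 lay at a mean distance of 0.478 from the other 2 G133 libraries, which were 0.308 apart. A library from another of the 4 ages was argued against, since its nearest library of another age was 1.47 times as far as its nearest G133 library. Depth was argued against as well: after thinning, its mean distance to the other 2 was still 1.47 times the distance between them. A different stage of development stays open: 1.52% of its squared deviation lay along the straight line from G85 to D42, but the other 2 lie off that line by 0.516, so the line decides nothing. It lay nearer than they did to both G85 (0.709 against 0.86 and 0.851) and D42 (0.709 against 0.759 and 0.793), and differences in dissection site, cell composition, handling or genotype may also remain, untested.

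On the median-ratio scale 336 genes rose both from G85 to G133 and from D42 to D243, steps with no library in common, against 145.9 for independent lists, and 211 fell at both, against 108.5; the correlation across genes, which are not independent replicates, was 0.213. The overlaps depend on single libraries: shared rises numbered 218 without G85 replicate 1, 217 and 205 without D42 replicates 1 and 2 and 207 without D243 replicate 1, and shared falls 133 without G85 replicate 1, 317 without G133 replicate 1, 92 and 91 without D42 replicates 2 and 3 and 123 without D243 replicate 1, with 1.52 to 2.67 times the number for independent lists over all 12 removals. Opposite directions on the median-ratio scale were a rise then a fall for 103 genes, against 89.8 for independent lists, and a fall then a rise for 124, against 176.5. As deposited, 69 rose and 990 fell at both, against 22.1 and 775.1 for independent lists. The rises ranged from 36 (without D42 replicate 3) to 104 (without G133 replicate 1), and the falls from 348 to 1741 without the same libraries. A hypothesis is that part of the same programme runs at both steps, but chance differences between libraries could account for the correlation: 14 of 100 combinations of splits of the 2 sets of 6 libraries gave one as far from 0 (highest other 0.293), as did 11 of the 40 that part all 3 animals (highest other 0.293). After the trend of each change with abundance was removed, the correlation was 0.177. Other splits gave up to 0.293 without that removal, so the value does not decide whether such a trend was the cause. Among 9982 genes of at least 10 CPM the correlation was 0.243. That value adds no support, since counting noise gives no correlation between steps without a shared library (-0.00156 in simulations with no effect).

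The counts of changed genes were also set against other splits of the same libraries. For all 4 ages, the real split was set among splits drawn at random, 100 in all. Only 1 of the 100, the real one, gave as many as 13931 genes, and the highest other gave 9337. A random split thus seldom called as many genes, though splits outside the draw were not tried. The draw treated all 12 libraries as independent, although D42 and D243 carry the same 3 animal numbers, so this share is approximate. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes at each step. From G85 to G133 the real split gave 8263 and the highest other 1, from G133 to D42 7452 and 0, and from D42 to D243 2029 and 1. Among the 4 splits of the last step that part all 3 animals, the highest other gave 0.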
